A study of Mus musculus with 6 samples.

How the data were processed

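The series holds 6 RNA-seq libraries of primary mouse gingival fibroblasts, 3 irradiated with an Er:YAG laser and 3 not, all of total RNA. Per the submitters' processing notes, Trimmomatic 0.39, FastQC 0.11.9, HISAT2 2.2.1 and StringTie 2.1.7 were used, with build GRCm39; their order and settings are not given in the sources used here. The strand setting and annotation release are also not given in the sources used here. The deposited table holds, per the file headers, DESeq2 results and one normalized count per gene and library, a signal that the authors made by dividing gene counts by 1 size factor per library. The authors also deposited a log2 fold change with its standard error, a test statistic (a score) and a p-value with its adjusted p-value for each gene, per the file headers. Of 20745 deposited rows, 80 repeated a gene identifier and were dropped, leaving 20665 genes; the lowest total over the 6 libraries was 3 reads. No coordinates are printed, because the annotation used here belongs to another build than the authors' one.

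Dividing each library's values by its smallest step gave whole reads for 100% of values within 0.001 reads. These recovered reads summed to 45178137 to 59904715 per library. A gene at 10 normalized counts therefore rests on about that many reads, and its values carry large counting error. Reads shared between parent genes and near-identical copies, or between overlapping genes, could be split by the authors' counting, so such genes are uncertain.

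Groups were taken from the sample titles. Genes with at least 10 normalized counts in at least 3 libraries (16141) were compared on log2(normalized count + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), without a block, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. The 2 groups of 3 leave 4 residual degrees of freedom, and the fit with the replicate block 2. The 30 gene lists, with 599 members of which 541 had a tested gene, were fixed before the data were examined, as was this test; 15 genes are in more than 1 list. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists, beside an estimated correlation and fry. Each list is also given with the count adjusted over the list alone.

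The replicate numbers come from the sample titles, and whether they mark shared cultures is not stated. They were checked from the values: over 13053 genes with a mean of at least 50 normalized counts, deviations from the group means correlated across genes at 0.64, 0.47 and 0.56 between same-numbered libraries, against at most 0.03 between libraries of different numbers. Replicate number took 70.9% of the sum of squares, irradiation 9.56% and the remainder 19.5%, where chance gives 40%, 20% and 40%. The numbers were therefore taken to pair the libraries, before the calls of the 2 fits were compared. A DESeq2 1.42.0 refit on the recovered reads with the replicate number as a term came within 0.0009 of every log2 fold change in the authors' deposited table, against differences of up to 8.61 without it.

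The named genes follow a rule fixed before the data were examined. As fewer than 5 genes passed, it takes the 10 genes with the smallest p whose groups do not overlap, with a mean of at least 50 normalized counts, leaving out unnamed gene models. It adds up to 2 members of each list with none past the threshold, by smallest p, and the 5 genes on each side of smallest adjusted p in the authors' deposited table. Genes outside it are named as chosen after their values were seen.

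The tests were run on simulated data with 200 changed genes among 16141, drawn from the real pair means and library sizes, in 5 draws for each of 2 kinds of dispersion. With dispersions following the trend, limma without the block recovered 0.60%, 21.2% and 74.2% of changes of 1.5-fold, 2-fold and 4-fold, and with the block 54.9%, 80.9% and 97.6%. With dispersions of each gene's own, 10.7% of the blocked limma calls were false over the 5 draws, from 4.24% to 21.2% per draw, and 12.2% of the blocked DESeq2 calls, above the 5% the threshold sets. Without the block 0% of limma calls were false. Camera recovered a shift of 0.3 (log2) of the immediate early list in 5 of 5 draws, with 0 other lists called; the simulated genes were independent, so correlation between genes was not tested there.

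Alternatives, planned before the data were examined, were other pseudocounts (0.5 and 5), no filter or a filter of 50, 3 other scalings, limma without trend or robust, the replicate block, edgeR 4.0.16, DESeq2 and voom on the recovered reads, the authors' deposited DESeq2 results, and leaving out each library. Alternatives added after seeing the data joined the block with other tools, scalings or left-out pairs. For the closing section, gene lengths and overlaps and transcript sequences came from GENCODE release M21, matched by gene identifier or symbol.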

Results

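RNA was measured in primary gingival fibroblasts, the connective tissue cells of the gum, from C57BL/6 mice. In 3 libraries the cells had been irradiated with an Er:YAG laser, an infrared laser whose light water absorbs strongly and which is used on teeth and gums. The energy density was 3.9 J/cm2 from a distance of 25 cm, onto a 35-mm dish. The other 3 libraries came from non-irradiated cells, and both groups were collected at 3 h. The 6 libraries held 45178137 to 59904715 gene-assigned reads. Col1a1, which encodes a chain of type I collagen, took the largest share in each library, from 1.54% to 2.02%. Mitochondrially encoded genes took 1.85% to 2.01%. Nothing in the labels says whether the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, part of which may be technical. Same-numbered libraries of the 2 groups deviated together, and 2165 of 16141 genes differed between the replicate numbers in limma with the block (adjusted p under 0.05). Values with the replicate number as a block are printed where they change a call.

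The comparison of irradiated with non-irradiated cells asked how laser light alters gene expression early after exposure. Immediate early and growth factor genes rose as lists in irradiated cells in a test with a preset correlation (adjusted p = 7.11e-09 and 0.0171 in camera, and adjusted p = 0.935 for both with an estimated correlation). Rps27a and 2 pseudogenes of Rps13 fell in limma with the replicate block. Nr4a1, an orphan nuclear receptor induced within minutes to hours of many stimuli, had 3726 ± 678 normalized counts (SD, n = 3) in non-irradiated and 6597 ± 1601 in irradiated cells. Its log2 fold change was 0.81 ± 0.21 (SE), and it was higher in 3 of 3 pairs of same-numbered libraries. Rps27a, which encodes a ubiquitin fused to a ribosomal protein, had 15982 ± 2309 and 9103 ± 1108 normalized counts, a log2 fold change of -0.81 ± 0.14 (SE). Of 16141 genes tested, 0 passed an adjusted p of 0.05 in limma, so 0 were called higher and 0 lower. At an unadjusted p under 0.05 there were 132 genes, where 807 would be given by chance. On reads recovered from the values, without the block, edgeR called 0 genes, with 112 at an unadjusted p under 0.05. The voom test called 0, with 146, and DESeq2 called 5, all lower, with 213. With the replicate block limma called 3 genes, all lower, with 526 at an unadjusted p under 0.05, edgeR called 2 and voom 3. The 2 groups did not overlap in 764 genes, 4.73% of those tested. Chance gives 10%, and the 807 genes above, for 6 exchangeable libraries, which libraries that deviate in pairs are not.

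The 3 genes that fell in limma with the replicate block were Rps13-ps1 (adjusted p = 0.0227), Rps27a (adjusted p = 0.0227) and Rps13-ps2 (adjusted p = 0.0379). Rps13-ps1 went from 950 ± 187 to 336 ± 56.5 normalized counts (SD, n = 3), and Rps13-ps2 from 880 ± 209 to 273 ± 69.1. Their log2 fold changes were -1.49 ± 0.14 and -1.69 ± 0.18 (SE with the block), against -0.81 ± 0.08 for Rps27a, and each was lower in 3 of 3 pairs. Rps13-ps1 and Rps13-ps2 are processed pseudogenes, intronless copies of the gene of a small-subunit ribosomal protein. The sum over Rps27a and its 2 listed pseudogenes had a mean log2 ratio over the pairs of -0.40 ± 0.12 (SEM, n = 3), so these genes are uncertain where reads of near-identical copies could be split. The parent Rps13 had a mean log2 ratio of 0.06 ± 0.16 over the pairs. Rps26-ps1 had a log2 fold change of -1.57 ± 0.25 (SE with the block) and did not pass in limma with the block (adjusted p = 0.364). It was called lower in DESeq2 without the block (adjusted p = 0.000817).

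**Figure D1:**
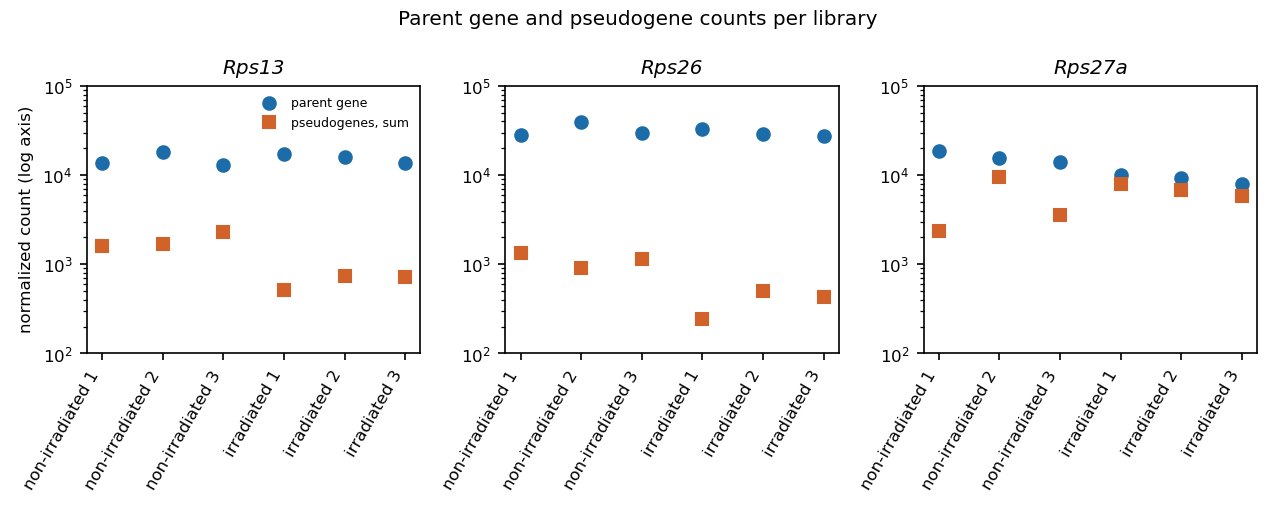
Normalized counts (log axis) in each of the 6 libraries for the parent genes Rps13, Rps26 and Rps27a and for the sum of their listed pseudogenes. Rps13 pseudogenes sum to between 1620 and 2334 in non-irradiated and between 518 and 743 in irradiated libraries, while Rps27a lies between 13988 and 18512 and between 7915 and 10109.

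By the rule for named genes, the 10 genes with the smallest p in limma without the block were Rps13-ps1, Rps13-ps2, Rps27a, Rps26-ps1, Egr2, Dusp4, Nr4a1, B3gnt2, Vegfa and Lrrc73, and none passed the threshold. Egr2, a zinc finger transcription factor of the early growth response family, had 785 ± 83.5 normalized counts (SD, n = 3) in non-irradiated and 1157 ± 106 in irradiated cells. Dusp4, a phosphatase that inactivates MAP kinases, had 6277 ± 610 and 8352 ± 438. Vegfa, the main growth factor of blood vessels, had 8947 ± 1181 and 13098 ± 2185. B3gnt2, a glycosyltransferase, had 1336 ± 41.0 and 1732 ± 90.2, and Lrrc73 had 149 ± 19.7 and 243 ± 16.4.

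There were 24 genes with an adjusted p under 0.05 in the authors' deposited table, 16 higher and 8 lower in irradiated cells, with 476 at an unadjusted p under 0.05. The smallest adjusted p of the higher genes in the authors' deposited table belonged to Nr4a1 (log2 fold change 0.81, adjusted p = 6.58e-10 in DESeq2). Next in the authors' deposited table came Ereg, an EGF receptor ligand (log2 fold change 0.56), and Ptgs2, the inducible cyclooxygenase (0.56). Lif, a cytokine of the interleukin-6 family, had a log2 fold change of 0.96 in the authors' deposited table, and Vegfa 0.54. The lower genes of smallest adjusted p in the authors' deposited table were Rps27a, Rps13-ps1, Rps13-ps2, Rps26-ps1 and Gm44503, with log2 fold changes of -0.81, -1.49, -1.70, -1.56 and -5.01. Gm44503 had 63.4, 107 and 12.1 normalized counts in the non-irradiated and 12.0, 0 and 0 in the irradiated libraries. Its fold change therefore rests on values at or near 0, and it has an exon overlapping another gene's exon on the same strand. Of the other higher genes of the authors' deposited table, Dusp4 and Inhba are named by the rule. The rest of the higher genes of the authors' deposited table, named here after their values were seen, were Errfi1, Gm21992, Hbegf, Dusp5, Rgs16, Gm4631, Plaur, Sema7a and Nr4a2. Its other lower genes, also named after the values were seen, were Ugt1a6b, Gm4724 and Gm20634 in the authors' deposited table. Refitting DESeq2 on the recovered reads with the replicate number as a term called 24 genes, all 24 of them shared with that table, and without the term 5. Without replicate 1, 2 or 3 of both groups that refit called 45, 21 and 9 genes, of which 13, 11 and 5 were shared with the 24.

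**Figure D2:**
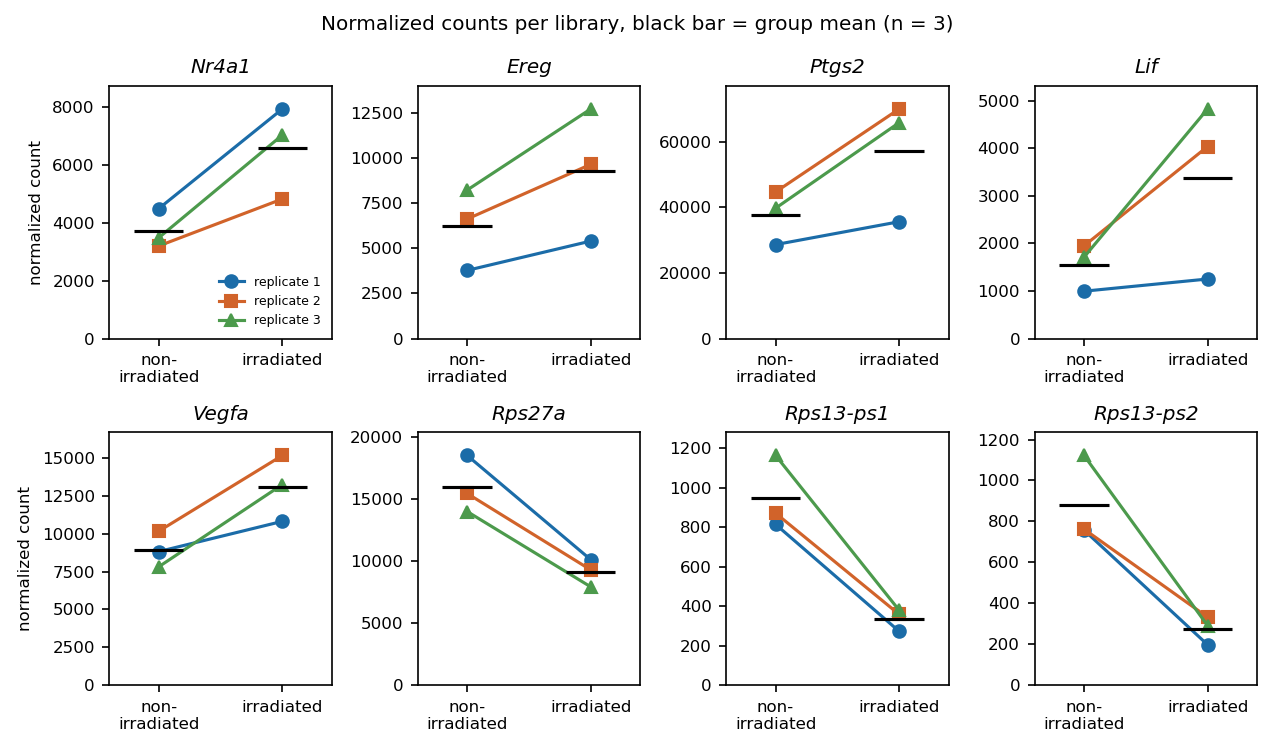
Normalized counts of 8 genes in each library, on linear axes from 0, with lines joining same-numbered libraries and black bars for the group means (n = 3). All 3 lines go up for Nr4a1, Ereg, Ptgs2, Lif and Vegfa and down for Rps27a, Rps13-ps1 and Rps13-ps2.

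Of 28 gene lists with at least 5 tested members, 5 passed an adjusted p of 0.05 in camera with a preset inter-gene correlation of 0.01, and 7 did with the replicate block. With an estimated correlation 0 lists passed in camera without or with the block, and the lists that passed at the preset one had an adjusted p = 0.935 without the block and an adjusted p = 0.907 with it. In fry, which asks whether a list's genes move one way on balance, the smallest adjusted p was 0.341 with the block. Across all tested genes 11.8% were higher in 3 of 3 pairs and 11.0% lower, where chance gives 12.5% each.

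Immediate early and early growth response genes, transcription factors and feedback regulators switched on without new protein synthesis, rose as a list. The median log2 fold change of the 33 members was 0.24, and 30 members had a positive value (camera adjusted p = 7.11e-09, and adjusted p = 0.935 with an estimated correlation). Of these members 22 were higher in 3 of 3 pairs. By gene, 0 of 33 passed over all genes in limma, or adjusted over the list alone. With the replicate block 0 passed over all genes, and 12 passed adjusted over the list alone, all higher: Nr4a1, Fosb, Dusp5, Nr4a2, Junb, Egr2, Fosl2, Btg2, Nr4a3, Dusp6, Maff and Srf. Those other than Nr4a1, Egr2 and Btg2 are named because they passed, after their values were seen. Fosb, a subunit of the AP-1 transcription factor, had 178 ± 97.8 normalized counts (SD, n = 3) in non-irradiated and 353 ± 198 in irradiated cells. Dusp5, an ERK phosphatase, had 2301 ± 831 and 3269 ± 1039. The list kept its call without each library in turn, with medians from 0.12 to 0.46.

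Growth factor genes also rose as a list, with a median log2 fold change of 0.14 over 25 members (camera adjusted p = 0.0171, and adjusted p = 0.935 with an estimated correlation). Of the members 17 had a positive value, and 12 were higher and 4 lower in 3 of 3 pairs. By gene 0 passed over all genes or adjusted over the list alone in limma without the block. With the block 0 passed over all genes and 5 adjusted over the list alone, namely Ereg, Lif, Vegfa, Hbegf and Inhba, all higher. Inhba, the activin A subunit, had 56096 ± 3033 normalized counts (SD, n = 3) in non-irradiated and 76180 ± 11597 in irradiated cells, and Ereg had 6215 ± 2257 and 9266 ± 3680. The list's call ended without non-irradiated replicate 1 (median 0.05), irradiated replicate 2 (0.16) and irradiated replicate 3 (-0.02), and without a filter on low values (adjusted p = 0.0589 in camera). Lif and Vegfa stand in 2 lists each.

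Hypoxia and glycolysis genes had a median log2 fold change of 0.07 over 23 tested gene identifiers, 21 of them positive (camera adjusted p = 0.0340, and adjusted p = 0.935 with an estimated correlation). Vegfa was the 1 member that passed adjusted over the list alone with the block, and 0 passed without it or over all genes in either fit. Aldoa is carried by 2 identifiers, of which the one with the smaller p had 17.3 ± 3.63 and 31.2 ± 6.18 normalized counts (SD, n = 3). The list's call ended without non-irradiated replicate 1 (median 0.11), non-irradiated replicate 3 (0.04), irradiated replicate 1 (-0.01) and irradiated replicate 2 (0.11). TGF-beta response genes had a median of 0.08 over 20 members, 16 of them positive and 9 higher in 3 of 3 pairs (camera adjusted p = 0.0462, and adjusted p = 0.935 with an estimated correlation). Of these 0 passed over all genes or adjusted over the list alone, with or without the block. Skil, a SMAD-binding repressor, had 4478 ± 553 and 5435 ± 625 normalized counts, and Bhlhe40, a transcriptional repressor, had 3531 ± 373 and 4547 ± 1043. Their list's call ended without non-irradiated replicate 1 (0.07), non-irradiated replicate 2 (0.06), irradiated replicate 2 (0.13) and irradiated replicate 3 (0.06). With quantile normalization the hypoxia list (adjusted p = 0.0536 in camera) and the TGF-beta list (0.209) did not pass, and without a filter on low values neither did these 2 (0.103 and 0.125). With the block and without both libraries of replicate 1, the hypoxia list (0.583) and the TGF-beta list (0.0564) did not pass, nor did the TGF-beta list with the block and quantile normalization (0.0786).

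A further 2 lists passed with the block and not without it: YAP and TEAD target genes and inflammatory cytokine and NF-kB target genes. The YAP and TEAD targets, genes read out by mechanical tension in many cells, had a median log2 fold change of 0.11 over 22 members (camera adjusted p = 0.142 without the block and 0.00963 with it, and adjusted p = 0.907 with the block and an estimated correlation). Ccn1, a secreted matrix protein, had 45650 ± 9383 normalized counts (SD, n = 3) in non-irradiated and 53896 ± 13522 in irradiated cells, and Lats2, a kinase that restrains YAP, had 9007 ± 842 and 10812 ± 2426. By gene 0 of these passed over all genes or adjusted over the list alone in either fit. The inflammatory list had a median of 0.08 over 22 members (camera adjusted p = 0.142 without the block and 0.0161 with it, and adjusted p = 0.907 with the block and an estimated correlation). With the block 0 of its members passed over all genes and 2 adjusted over the list alone, Ptgs2 and Lif, both higher, and 0 did in either way without the block. Ptgs2 had 37697 ± 8221 and 57153 ± 18766 normalized counts, and Lif 1553 ± 497 and 3375 ± 1880. Without the block, the YAP and TEAD list was called higher without non-irradiated replicate 3 (median 0.23) or irradiated replicate 1 (0.15) and in voom (0.09, adjusted p = 0.0432 in camera), and the inflammatory list without irradiated replicate 1 (0.22). Without both libraries of replicate 3, the blocked fit called 1 list, the immediate early one, and without those of replicate 2 the YAP and TEAD list did not pass (adjusted p = 0.275 in camera).

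Cytosolic ribosomal protein genes fell as a list by a median of 0.08 on the log2 scale, with 33 of 34 members below 0 (camera adjusted p = 0.0171, and adjusted p = 0.935 with an estimated correlation). None of the 34 was lower in 3 of 3 pairs, and 0 passed over all genes or adjusted over the list alone, with or without the block. Rps19 had 31332 ± 5390 normalized counts (SD, n = 3) in non-irradiated and 27994 ± 2915 in irradiated cells, with log2 ratios of 0.13, -0.46 and -0.14 in the pairs of replicates 1, 2 and 3. Rplp2 had 21581 ± 5209 and 18805 ± 1699. The call ended without non-irradiated replicate 2, where the median was 0.03, without irradiated replicate 2 (-0.09) and without irradiated replicate 3 (-0.03), and also without a filter on low values (adjusted p = 0.0589 in camera). With the block it ended without both libraries of replicate 2 (median 0.03, adjusted p = 0.378) or of replicate 3 (-0.09, adjusted p = 0.376).

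Stress programs did not pass. Heat shock and chaperone genes had a median log2 fold change of 0.03 over 22 members (camera adjusted p = 0.777), and Dnajb1, a co-chaperone of Hsp70, had 2594 ± 210 and 2806 ± 204 normalized counts (SD, n = 3), with Dnajb4 at 2474 ± 167 and 2800 ± 381. Unfolded protein and integrated stress response genes had a median of -0.07 over 20 (adjusted p = 0.142, and 0.0503 in camera with the block), with Herpud1 at 4342 ± 328 and 3863 ± 419. NRF2 and oxidative stress genes had a median of 0.02 over 21 (camera adjusted p = 0.496), and Txnrd1, a thioredoxin reductase, had 21234 ± 1931 and 25683 ± 523 normalized counts. p53 target genes had a median of 0.01 over 21 (camera adjusted p = 0.554), and Plk2 had 6984 ± 760 and 8290 ± 729. Interferon-stimulated genes stood at 0.02 over 18 (camera adjusted p = 0.934), with Irf1 at 594 ± 91.7 and 483 ± 137. Heat shock genes were called higher without non-irradiated replicate 2 (median 0.12), as were NRF2 genes (0.065). Unfolded protein response genes were called lower without non-irradiated replicate 3 (-0.13), and in voom (-0.08). With the block they were called lower in voom (adjusted p = 0.00208 in camera) and with TMM on top (0.0379), equal library totals (0.0269) or quantile normalization (0.0110). By gene 0 members of these 5 lists passed over all genes or adjusted over the list alone, with or without the block.

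Cell cycle lists did not pass either. G1 and S phase genes had a median log2 fold change of 0.01 over 26 members (camera adjusted p = 0.934), with E2f1 at 1240 ± 204 and 1340 ± 75.3 normalized counts (SD, n = 3). G2 and M phase genes had a median of -0.0008 over 25 (camera adjusted p = 0.934), and Foxm1, a driver of mitotic genes, had 2841 ± 317 and 3287 ± 791. The G2 and M list was called higher without non-irradiated replicate 2 (median 0.13) or irradiated replicate 1 (0.18), and lower without irradiated replicate 2 (-0.16). G1 and S genes were called higher without non-irradiated replicate 2 (0.12) or irradiated replicate 1 (0.14). By gene 0 members of both lists passed over all genes or adjusted over the list alone in either fit.

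Collagen and extracellular matrix genes had a median log2 fold change of 0.05 over 24 members, 23 of them positive (camera adjusted p = 0.261). Tnc, the matrix protein tenascin C, had 64931 ± 2864 and 74709 ± 7257 normalized counts (SD, n = 3). This list was called higher without non-irradiated replicate 1 (0.28) or irradiated replicate 2 (0.20). With the block it was called higher in voom (adjusted p = 0.00676 in camera) and without both libraries of replicate 1 (median 0.14, adjusted p = 0.00548). Matrix protease and inhibitor genes had a median of 0.01 over 19 (camera adjusted p = 0.554). With the block 0 of them passed over all genes and 2 adjusted over the list alone, Plau and Plaur, the urokinase protease and its receptor, both higher. Plau had 16224 ± 2994 and 20669 ± 1840 normalized counts. In fry's test for change in either direction, the protease list had an adjusted p = 0.0042 with the block and 0.988 without it. In its directional test this list had an adjusted p = 0.492 with the block. Osteogenic genes had a median of 0.13 over 12 (camera adjusted p = 0.415), with Runx2, the master regulator of bone formation, at 3280 ± 667 and 3868 ± 1220. With the block the osteogenic list was called higher in voom (adjusted p = 0.0108 in camera) and with quantile normalization (0.0376). Wnt pathway genes had a median of -0.03 over 16 (camera adjusted p = 0.901), with Ccn4 at 13877 ± 3485 and 16191 ± 1102. With the block the Wnt list was called lower without both libraries of replicate 2 (median -0.16, adjusted p = 0.0304 in camera). Of the collagen, osteogenic and Wnt genes 0 passed over all genes or adjusted over the list alone in either fit.

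Metabolic and signalling lists did not pass. Cholesterol synthesis genes had a median log2 fold change of -0.001 over 21 members (camera adjusted p = 0.934). Circadian and glucocorticoid response genes had a median of 0.02 over 19 (camera adjusted p = 0.827), with Tsc22d3, a glucocorticoid-induced gene, at 1762 ± 9.28 and 1584 ± 13.9 normalized counts (SD, n = 3). Nuclear cytochrome c oxidase subunit genes had a median of -0.09 over 10, with 0 above 0 (camera adjusted p = 0.142), and Cox5b had 4169 ± 1077 and 3498 ± 145. This list was called lower without non-irradiated replicate 1 (median -0.18) and in voom (-0.10, adjusted p = 0.0432 in camera). With the block it was called lower in voom (adjusted p = 0.0113) and without both libraries of replicate 1 (-0.22, adjusted p = 0.00856). Mitochondrially encoded genes had a median of 0.02 over 13 (camera adjusted p = 0.934), with mt-Co3 at 56421 ± 3302 and 51513 ± 5278. Inositol phosphate and calcium signalling genes had a median of 0.06 over 27 (camera adjusted p = 0.261), with Orai1, a calcium channel, at 540 ± 18.4 and 465 ± 20.05. By gene 0 members of these 5 lists passed over all genes or adjusted over the list alone in either fit. Camera put the mitochondrially encoded and the circadian genes lower although their medians were above 0, and the cholesterol genes higher although theirs was below 0.

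Markers of cell types were compared as a check of the cultures. Fibroblast markers had a median log2 fold change of 0.02 over 12 members (camera adjusted p = 0.827), with Pdgfra, a receptor on fibroblasts, at 12268 ± 2035 and 13411 ± 1962 normalized counts (SD, n = 3). Pericyte and smooth muscle markers had a median of 0.13 over 8, all above 0 (camera adjusted p = 0.356), with Cspg4 at 19459 ± 2961 and 21473 ± 1655. With the block this list was called higher without both libraries of replicate 1 (median 0.21, adjusted p = 0.0175 in camera). Endothelial markers had a median of 0.14 over 7 (camera adjusted p = 0.777) and macrophage and leukocyte markers 0.02 over 6 (0.934 in camera), with Csf1r at 226 ± 31.6 and 256 ± 56.7 and Cdh5 at 18.5 ± 13.4 and 24.3 ± 11.7. Schwann and neural crest markers had a median of -0.04 over 8 (camera adjusted p = 0.934), with Ngfr at 2958 ± 449 and 2723 ± 611. Camera put the macrophage markers lower and the Schwann markers higher, against the sign of their medians. Epithelial markers (median -0.12 over 4) and skeletal muscle markers (0.02 over 4) had too few tested members for a test. Of the cell type markers 0 passed over all genes or adjusted over the list alone, with or without the block.

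**Figure D3:**
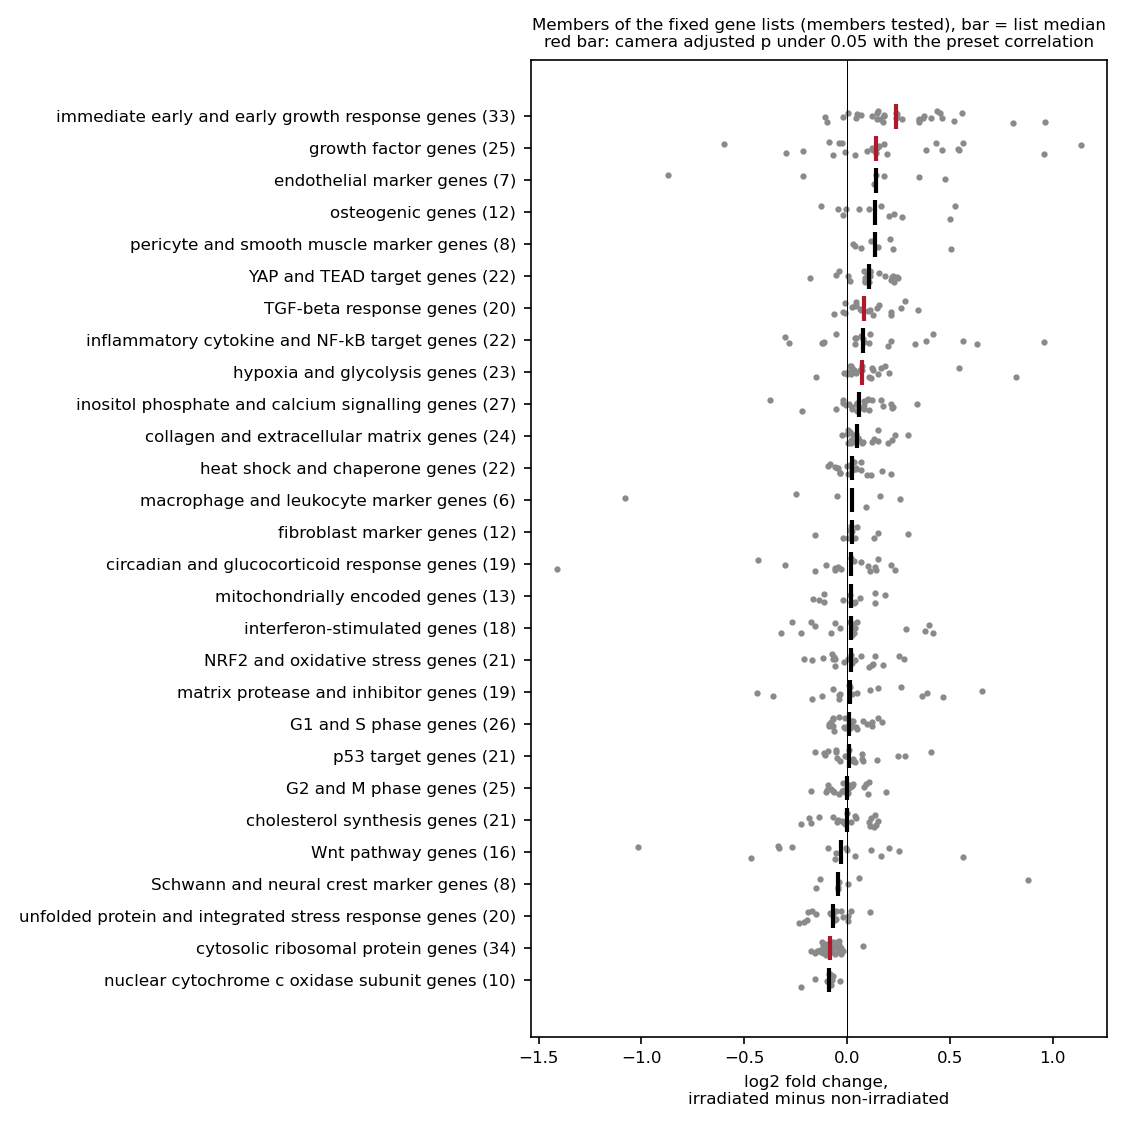
Log2 fold changes (irradiated minus non-irradiated, grey points) of the members of the 28 tested gene lists, with a bar at each list's median, red where camera with the preset correlation gave an adjusted p under 0.05. The immediate early list has the highest median, 0.24, and the red bars are lost with an estimated correlation.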

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

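Tests that joined the replicate block with another tool, scaling or left-out pair were chosen after the data were seen; the others were planned. The number of genes past the threshold in limma was 0 with both other pseudocounts, both other filters, all 3 other scalings, the robust fit, an adjusted p under 0.1, and edgeR and voom without the block, with 132 genes at an unadjusted p under 0.05 in the fit as reported. Limma without a trend called 1 gene, which was higher (Ccdc60). Leaving out single libraries gave 0 to 1, the 1 being lower (Usp50, without irradiated replicate 3). DESeq2 without the block called 5, all lower. With the replicate block limma called 3, edgeR 2 and voom 3, all lower, and the block with TMM on top, equal totals (CPM) or quantile normalization called 3 each, all lower. DESeq2 with the replicate block called 24 genes, 16 higher and 8 lower, as did the authors' deposited DESeq2 results. With the block and without replicate 1, 2 or 3 of both groups, limma called 36, 32 and 64 genes (higher 18, 18 and 28, lower 18, 14 and 36). DESeq2 then called 45, 21 and 9 (higher 35, 12 and 3, lower 10, 9 and 6); these fits leave 1 residual degree of freedom, and the cause of their higher limma counts was not tested.

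The number of gene lists past the threshold, 5 as reported, was 1 with no filter on low values, 3 with quantile normalization, 8 with voom and 11 with voom and the replicate block. It was 7 with the replicate block, and 8 with the block and TMM on top, 8 with equal totals (CPM) and 8 with quantile normalization. A correlation estimated from the data gave 0, and 0 with the replicate block. Leaving out single libraries gave 2 to 8 lists, with 8 without irradiated replicate 1, 3 without irradiated replicate 2 and 2 without irradiated replicate 3. With the block, 8, 6 and 1 passed without replicate 1, 2 and 3. List medians changed sign where a call was made or lost: growth factor genes to -0.024 without irradiated replicate 3, hypoxia and glycolysis genes to -0.0063 without irradiated replicate 1, and cytosolic ribosomal protein genes to 0.035 without non-irradiated replicate 2 and to 0.032 with the replicate block, without replicate 2. G2 and M phase genes went to 0.13 without non-irradiated replicate 2 and to 0.18 without irradiated replicate 1. Over all left-out libraries their medians ran from -0.024 to 0.37, -0.0063 to 0.14, -0.16 to 0.035 and, for G2 and M phase genes, -0.16 to 0.18. The cause was not tested for any of these. A fit without the block and without 1 library keeps that library's same-numbered partner, so differences between pairs enter the comparison. Replicate number took 70.9% of the sum of squares, and 80% of G2 and M phase genes differed between pairs. Calls gained or lost in such fits therefore mix differences between pairs with any difference by irradiation. In the simulation the fit without the block recovered 0.60% of 1.5-fold and 21.2% of 2-fold changes, so its counts of 0 say little on changes of that size. Limma with the block recovered 54.9% and 80.9% of them there, and called 3 genes in the real data. These shares hold for 200 changed genes, and adjusted p-values depend on how many genes change. They therefore do not show how many such changes the real data hold. Nr4a1, with a log2 fold change of 0.81, had an adjusted p = 0.0908 in limma with the block. Recovered and lost calls were not compared by depth.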

Other observations

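The tests of cells of another type, of the Rps27a pseudogenes, of general falls of ribosomal protein genes or pseudogenes and of irradiation on genes counted in some libraries were chosen after the result was seen. The comparison of pairs and its gene selection were also made after the data were seen. Same-numbered libraries shared large differences from the other numbers: 2165 of 16141 genes differed between the 3 pairs in limma with the block (adjusted p under 0.05), or 13.4%. By list, 80% of G2 and M phase genes differed between pairs, 72.0% of growth factor genes, 68.4% of matrix protease genes and 66.7% of collagen and matrix genes, against 0% of ribosomal protein, cytochrome c oxidase and mitochondrially encoded genes. Some genes that pattern the embryonic face were among them, picked by hand after the values were seen and not tested as a set. Of those looked at, Dlx2 (adjusted p = 0.420), Tbx18 (0.357) and Hoxa2 (0.0718) did not pass between pairs. The series title gives the maxilla, the upper jaw, as the source of the cells. Pitx1, a homeobox gene of the lower jaw, had 1635 and 1498 normalized counts in the libraries of replicate 1, 489 and 516 in those of replicate 2 and 28.7 and 42.3 in those of replicate 3 (non-irradiated, then irradiated). Dlx5 had 420 and 488 in replicate 1 and between 50.02 and 109 elsewhere, and Hand2, which marks the lower part of the branchial arches, had 359 and 300 against 4.42 to 18.3. Alx1, a homeobox gene of the frontonasal region, went the other way, with 25.4 and 15.3 in replicate 1 and between 1350 and 2081 elsewhere. Alx4 had 0 and 6.56 in replicate 1 and between 1436 and 3078 elsewhere, and Pax3 had 438 and 317 against 1510 to 3161. Igfbp2, a carrier of insulin-like growth factors, had 2052 and 2016, 14477 and 12457, and 75202 and 77631 in replicates 1, 2 and 3. Col2a1, the collagen of cartilage, had 2518 and 2335, 248 and 336, and 11302 and 12990, and the imprinted H19 6182 and 5461, 102 and 80.2, and 1657 and 1418.

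Some genes had log2 ratios of irradiated to non-irradiated cells with 1 sign in pair 1 and the other in pairs 2 and 3. Swapping the 2 labels of replicate 1 gave 122 genes in DESeq2 with the block, against 24 for the real labels. The swap selects genes for these opposite signs, and with 1 library per group in a pair, a response that differs between pairs is not separated from differences between single libraries. Raver1 had log2 ratios of 0.86, -0.81 and -0.82 in pairs 1, 2 and 3, Rpl17 of 0.95, -0.71 and -0.73, Mt1, a metallothionein, of 0.36, -0.63 and -0.36, and the matrix protein Aspn of -0.40, 0.57 and 0.56. By the fixed lists, immediate early genes gave 0 of the 122, cytosolic ribosomal protein genes 4 and NRF2 and oxidative stress genes 3. Ribosomal protein genes outside the fixed list were also among the 122, such as Rpl17, Rps27, Rps28 and Rps29. The swap selects against genes that move the same way in 3 of 3 pairs. Of 33 immediate early genes 22 were higher in all of these pairs, so their 0 says little.

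Immediate early and growth factor genes were higher as lists in irradiated cells, and 4 explanations were set against tables. A trend with expression level or transcript length is argued against: the immediate early median of 0.24 lay at a percentile of 100 among 10000 lists matched on both. A hypothesis is that the irradiated cells had higher output of the ERK pathway. The 15 ERK output genes outside the fixed lists were chosen after the calls were seen but before their own values. They had a median of 0.14 ± 0.08 (SE from resampling genes, as for the other medians of this section). This lay at a percentile of 99.95, and at 91.8 when the median is lowered by 1 SE. Their log2 fold changes ran from -0.09 (Epha4) to 0.45 (Spry4). Matched lists were drawn gene by gene, so the percentiles take no account of correlation between the genes of a list, and ERK output stays open. For 13 cAMP and CREB targets the percentile was 88.0, with a range of 49.97 to 98.9 over 1 SE, so this stays open. Cells of another type cannot be told apart from a response on these values. The 17 tested markers of 3 other cell types had a median of 0.024 ± 0.11 (SE). Their median level was 34.6 normalized counts, near the floor. The 8 pericyte and smooth muscle markers, at a median level of 4622, had a median of 0.13 and were all above 0. As a list they did not pass in camera (adjusted p = 0.356, and 0.0789 with the block). They were called higher with the block and without replicate 1 (median 0.21, camera adjusted p = 0.0175).

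Rps27a and the Rps13 and Rps26 pseudogenes were lower in irradiated cells. A general fall of ribosomal protein pseudogenes as large as theirs is argued against, as the other 115 had a median of -0.12 ± 0.02 (SE). So is a fall of ribosomal protein genes as large as that of Rps27a, as their list had -0.083 ± 0.012. Both medians were negative, so a smaller general fall stays open. Their SE comes from resampling genes and does not measure the spread between libraries. For the ribosomal protein list the estimated correlation between genes was 0.92. None of its 34 members was lower in 3 of 3 pairs, and its median was 0.03 with the block without replicate 2. Reads of the parent gene counted on the pseudogenes may be part of the fall of the Rps13 and Rps26 pseudogenes. Of the 50-base windows of Rps13-ps1, Rps13-ps2 and Rps26-ps1, 79.5% are found unchanged in a parent transcript. A small shift in how reads were assigned could therefore move these genes while the parents stay put. The parents were at 0.06 ± 0.16 and -0.11 ± 0.19 (mean log2 ratio ± SEM over the 3 pairs). For Rps27a the sum with its pseudogenes fell by 0.40 ± 0.12, close to 0.5 of its own fall of 0.81 ± 0.04. In pairs 1, 2 and 3 the sum of the pseudogenes alone had log2 ratios of 1.75, -0.47 and 0.69. It was thus higher where Rps27a was lower in 2 of 3 pairs. Both pseudogenes were among the 32 genes called in limma with the block without replicate 2. That fit leaves out the pair in which the pseudogenes fell as a sum, so its calls do not bear on the question. Reads counted on the pseudogenes instead and a change of Rps27a itself cannot be told apart here. The sum with Rps27a lies within 1 SE of the bound between them. That margin of 1 SE was added after the value was seen, and without it the sum falls on the side of reads counted on the pseudogenes.

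Some genes were counted in part of the libraries and at or near 0 in others: 139 had at least 50 normalized counts in 1 library and at most 2 in another. Irradiation is argued against as the source of most of them: of 115 with no tied pair, 23.5 ± 3.95% (SE) moved the same way in 3 of 3 pairs, where chance gives 25%. Reads of overlapping genes on the same strand counted on either gene are a candidate source: 32.4% of the 139 had an exon overlapping another gene's exon on the same strand, 3.94 times the 8.21% of other genes of similar level. Gm28036 had 2148, 143, 1865, 3729, 2267 and 0.96 normalized counts in the 3 non-irradiated and then the 3 irradiated libraries. Alx4 is also among the 139, has no such overlap and differed between pairs.

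The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 genes in limma and the highest other 1, and 5 lists with a highest other of 14. Of the 10 splits 6, the real one included, gave at least 5 lists, so the number of lists does not set the real split apart. Among the 4 splits that part all 3 pairs, the fits with the replicate block gave 3 genes with a highest other of 10. They gave 7 lists with a highest other of 7, and 24 genes in DESeq2 with a highest other of 122. For each of these counts 2 of the 4 splits, the real one included, reached the real value. The highest counts of genes with the block came from the split that swaps the labels of replicate 1. This may reflect a structure of the samples, whose cause was not tested, though 1 of 4 splits must be highest. The 14 lists came from the split that sets irradiated and non-irradiated replicate 3 with non-irradiated replicate 1.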
